A study of Abies pinsapo with 12 samples.

How the data were processed

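RNA was sequenced from needles of adult Spanish fir (Abies pinsapo) growing in the field in southern Spain. Trees stood in 3 field treatments, with 3 plots of 100 m2 per treatment. Control trees grew in dense stands that had not been thinned. Thinning trees grew where tree density had been lowered in 2004. Trees with thinning plus shading grew in thinned stands under a mesh that brought the light down to about that of the control stands. Needles were taken in August 2016 and in May 2017, and each treatment and month has 2 libraries, so that 12 libraries fall into 6 groups. Groups and replicate numbers were taken from the sample titles, and each deposited column was matched to its sample by the sample's description. Nothing in the labels says that the 2 replicates of a group came from separate trees, or that the same trees were sampled in both months, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, samples with an RNA integrity number above 7 went on to poly(A) selection, and TruSeq libraries were read on an Illumina HiSeq as paired reads of 150 bp. The same protocol text speaks of RNA from roots of maritime pine seedlings, whereas the tissue and organism labels of all 12 samples say fir needles; the samples were treated as fir needles.

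The deposited table lists 329801 transcripts, each an identifier in the form that the Trinity assembler gives to the genes of a de novo assembly. By their DN numbers they fall in 260474 clusters. A component, as counted below, is given by the DN number and the c number together, so 1 cluster can hold several components. The submitters' processing notes name Trimmomatic, RSEM and DESeq2, without versions or settings; the assembly, the way the values were scaled and any filter are not given in the sources used here. The deposited values are a signal that was worked out from the values themselves. Each column sums to between 856638 and 1179097, and after a column is rescaled to the common TPM total, at least 99.35% of its values above 0 lie within 0.1 step of a multiple of 0.01. The deposited values are therefore TPM values (a transcript's share of its library after correction for length, on a fixed total) with 2 decimals, multiplied by 1 factor per library, and the 12 factors have a geometric mean of 1. They are called scaled TPM here. TPM keeps no sequencing depth, so the depth of each library is unknown, no count of reads could be recovered, and no counting interval is given. Tests that need whole reads were not run for the same reason. The table does not pair the identifiers with gene names, and no annotation was used here. The lists of pathways and marker genes fixed before the data were examined could therefore not be applied, and transcripts are given by identifier alone, with no function. Several transcripts of 1 component can be near-identical copies or fragments of 1 gene between which reads are shared, so their values are not independent.

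Differences were tested with limma 3.58.1 in R 4.3.3 on log2(scaled TPM + 1). The 19726 transcripts with a value of 10 or more in at least 2 libraries were tested; they hold between 71.4% and 90.0% of a library's summed value. All 12 libraries entered 1 fit with 6 group means and 6 residual degrees of freedom, with empirical Bayes moderation along an intensity trend. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each of 16 contrasts, and a transcript was called at an adjusted p under 0.05. The contrasts are August minus May as the mean of the 3 treatments and within each treatment, each pair of treatments as the mean of both months and within each month, and the difference between the months of each pair of treatments. Fold changes are on the log2(scaled TPM + 1) scale, which understates the change of low transcripts. Named transcripts follow a rule fixed before the data were examined: in a comparison, up to 2 called transcripts with the largest rise and 2 with the largest fall, with a mean of at least 50 in the higher group and every library of the higher group above every library of the lower one. Transcripts named outside that rule are said to be so.

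Both treatments were compared with the same control libraries, so the correlation and overlap of their differences were set beside 100 simulations in which the treated groups did not differ from those controls, and the shaded trees' values in the transcripts lower with thinning beside 100 in which only thinning without shading had an effect. The test was also run on simulated data in which 200 of the 19726 transcripts were changed by known folds, over 10 draws. The changed transcripts were drawn from those with a mean log2(scaled TPM + 1) at or above that of a value of 10. The recovery below therefore covers the more abundant transcripts only. In all these simulations the noise was independent between transcripts, which it is not in the data. For the month effect it recovered 50.6% of 2-fold and 84.2% of 4-fold changes, with a median of 24 false calls. For thinning against control within August it recovered 6.8% of 2-fold and 52.9% of 4-fold changes, with a median of 5.5 false calls, and within May 17.3% and 61.3%, with a median of 103 false calls. Quantities with 1 value per library were compared between months by a two-sided exact permutation test with SciPy 1.17.1, adjusted over the 5 quantities tested; the number of transcripts at 10 or more was also compared without the library factor, after the data had been seen.

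The alternatives fixed before the data were examined were quantile normalization, pseudocounts of 0.5 and 8, no filter, a filter of 50, fits of only the groups compared, the replicate number as a block, and leaving out each library in turn. TPM without the library factor, the first principal component of the residuals as a covariate, fits of 1 month and blocks with crossed pairs were added after the data had been seen. Principal components were computed over the 19726 tested transcripts. Figures were drawn with matplotlib 3.10.9.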

Results

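Needle transcripts of Spanish fir were measured in trees of 3 field treatments that set the competition for light and water apart: unthinned control stands, thinned stands, and thinned stands under a shading mesh. Each treatment was sampled in August 2016 and May 2017 with 2 libraries per month. Values are scaled TPM, that is, TPM times 1 factor per library, for 329801 assembled transcripts, of which 13909 were at 0 in every library. Sequencing depth is unknown. Libraries listed between 81710 and 117855 transcripts above 0, except thinning May replicate 1, which listed 208032. Between 13299 and 15076 transcripts per library were at 10 or more.

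By nearest library, the 12 libraries grouped by month. Each library correlated best with a library of its own month across the 19726 tested transcripts, which are not independent replicates. The months were not fully apart. Thinning May replicate 1 correlated at 0.748 with thinning August replicate 1, against 0.407 with its own replicate. On the first principal component, August libraries lay between -58.3 and -18.3 and May libraries between -42.4 and 172. The 2 replicates of a group correlated at r = 0.903 in control, 0.922 in thinning and 0.909 in thinning plus shading in August. In May the values were 0.729, 0.407 and 0.830. The root mean square SD between replicates was 0.518 log2 units in August and 1.01 in May. In May the libraries did not pair by treatment. Thinning replicate 1 correlated at 0.849 with control replicate 2, and thinning replicate 2 at 0.8595 with control replicate 1, against 0.407 with each other. The nearest library of thinning replicate 1 (r = 0.887) and of control replicate 2 (0.866) was thinning plus shading replicate 1. That of control replicate 1 was thinning plus shading replicate 2 (0.8615). Any May value of the thinning or control trees is therefore a mean over unlike libraries.

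**Figure D1:**
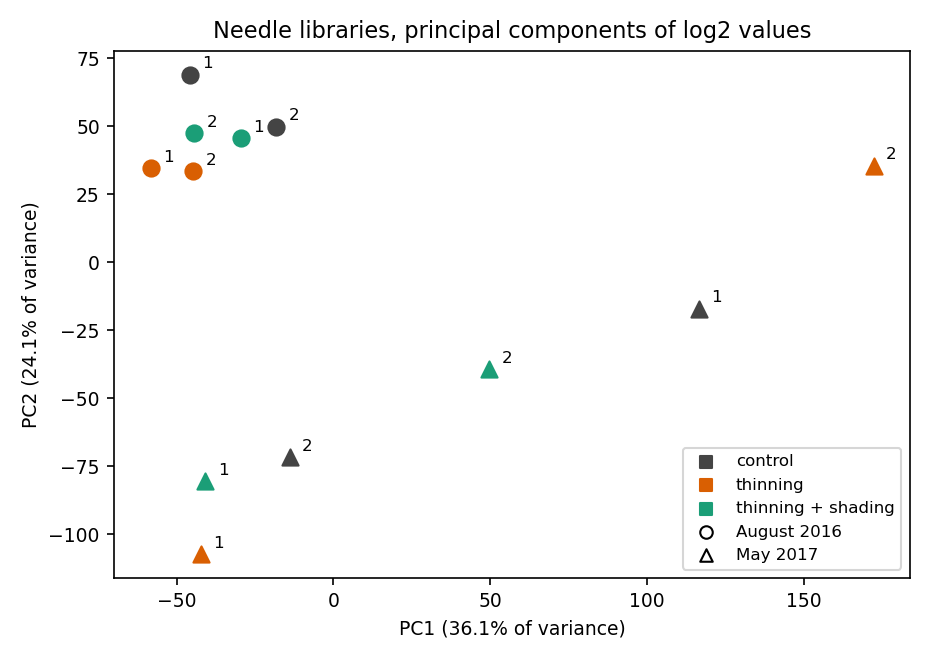
Principal components of log2(scaled TPM + 1) over the 19726 tested transcripts; each point is 1 library, colour gives the treatment, shape the month, and the digit the replicate. The horizontal axis holds 36.1% and the vertical axis 24.1% of the variance, and the 6 August libraries lie close together while the 6 May libraries are spread out.

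The needles sampled in August 2016 and in May 2017 differed in a large share of their transcripts. Each month was sampled once and in a different year, so season, year and any batch of sampling or sequencing cannot be told apart. TRINITY_DN15726_c0_g1 was at 2.36 ± 1.91 scaled TPM in May and at 1237 ± 1107 in August (mean ± SD, n = 6 libraries per month, log2 fold change 7.62, SE 0.80, limma adjusted p = 0.0028). TRINITY_DN4825_c0_g2 was at 0.413 ± 0.526 in May and at 179 ± 147 in August (log2 fold change 6.63, SE 0.57). TRINITY_DN180_c1_g1 was at 78.8 ± 109.6 in May and at 0.415 ± 0.397 in August (log2 fold change -4.43, SE 0.94; limma adjusted p = 0.019). TRINITY_DN1186_c1_g2 was at 61.7 ± 59.4 in May and 2.11 ± 2.41 in August (log2 fold change -4.21, SE 0.51). In all 4, every library of the higher month was above every library of the lower month. TRINITY_DN180_c1_g1 was lost with a pseudocount of 8 (limma adjusted p = 0.069) and with no filter (0.096), and without control August replicate 1, thinning August replicate 1 or 2, thinning plus shading August replicate 2 or thinning plus shading May replicate 1 (0.052 to 0.061); the other 3 kept their calls without any 1 of the 12 libraries. The rule fixed beforehand left 204 higher and 162 lower transcripts to choose from.

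Of the 19726 transcripts, 3102 were called between the months averaged over treatments, 1665 higher in August and 1437 lower (limma, adjusted p under 0.05). At 4-fold or more there were 215 higher and 159 lower. The median log2 fold change was 0.99 among the higher and -0.86 among the lower calls. In 2892 of the 3102 (93.2%) the change had 1 sign in all 3 treatments, which their choice by the mean of the treatments favours; over all 19726 transcripts the share was 52.4%. In 830 transcripts all 6 August libraries lay above all 6 May libraries, and in 881 all below, against 21.3 per direction by chance. The calls fell in 2233 assembly components, and 1686 of them shared a component with another call. The split into directions depended on the scaling: 53.7% of the calls were higher in August as deposited, 65.4% after quantile normalization and 86.7% without the library factor, which moved the median of all transcripts by 0.281 log2 units. The number of calls was 1327 without control August replicate 1 and 1975 without replicate 2, 1717 without control May replicate 1, 1426 and 1758 without thinning August replicate 1 and 2, 1878 and 1439 without thinning plus shading August replicate 1 and 2, 1509 and 1601 without thinning plus shading May replicate 1 and 2, and 6468 without thinning May replicate 1.

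Very abundant transcripts carried more of the May libraries. The 10 most abundant transcripts of a library held 11.5 ± 3.2% of its summed value in May and 5.56 ± 0.41% in August (SD, n = 6; two-sided exact permutation p = 0.0022, Benjamini-Hochberg adjusted 0.0036 over 5 quantities), with every May library above every August library. The 100 most abundant held 25.7 ± 4.8% and 18.1 ± 1.0% (n = 6; exact permutation p = 0.0022, adjusted 0.0036). TRINITY_DN3031_c1_g1 stood at 28606 ± 16590 scaled TPM in May and 2806 ± 1197 in August (n = 6; log2 fold change -2.87, SE 0.68; limma adjusted p = 0.027), but at only 1390 in thinning May replicate 2. Its log2 fold change was -1.63 after quantile normalization, with an adjusted p of 0.11 by limma, and its call was also lost with no filter (0.117) and in 10 of the 12 fits without 1 library (0.057 to 0.077), all but those without a thinning May library. TRINITY_DN7298_c0_g1 was at 24911 ± 6452 in May and 10352 ± 2155 in August (n = 6; log2 fold change -1.24, SE 0.32), and its log2 fold change was 0.37 after quantile normalization; its call was also lost with a pseudocount of 0.5, a filter of 50, without the library factor and in the same 10 of 12 fits without 1 library (0.073 to 0.125). A further transcript of that component, TRINITY_DN7298_c0_g2, was at 19026 ± 4895 and 7952 ± 1709, and its call was lost in the same 10 fits. The call was also lost with a pseudocount of 0.5 (limma adjusted p = 0.076) and a filter of 50 (0.084). After quantile normalization its log2 fold change was 0.39. These 3 were chosen after their values had been seen. The library factor itself was 1.112 ± 0.056 in May and 0.901 ± 0.031 in August (n = 6; exact permutation p = 0.0022, adjusted 0.0036). The number of transcripts at 10 or more depended on that factor: with it there were 14418 ± 572 in May and 13702 ± 355 in August (n = 6; exact permutation p = 0.032, adjusted 0.041), and without it 13353 ± 889 and 14790 ± 351 (n = 6; exact permutation p = 0.0087, outside the 5 quantities). The number at 1 or more did not pass (p = 0.080 by the exact permutation test).

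Within single treatments fewer transcripts were called between the months. Control trees gave 211, of which 188 were higher in August and 23 lower. Thinning trees gave 307, with 221 higher and 86 lower. Thinning plus shading gave 232, with 99 higher and 133 lower (limma, n = 2 libraries per group). Of 655 transcripts called in any treatment, 82 were called in the same direction in at least 2 treatments and 13 in all 3. The month effects, which share no libraries between treatments, correlated across transcripts at r = 0.520 between control and thinning, 0.557 between control and thinning plus shading, and 0.528 between thinning and thinning plus shading. Of the 211 transcripts called in control trees, 102 (48.3%) had the same sign in thinning trees and 192 (91.0%) in thinning plus shading, and of the 307 called in thinning trees 284 (92.5%) had it in thinning plus shading. Over all tested transcripts these 3 shares were 69.4%, 70.8% and 64.4%. The last of these correlations was 0.262 without thinning May replicate 1 and 0.611 without replicate 2. In thinning plus shading, 42.7% of the calls were higher in August as deposited, 55.3% after quantile normalization and 83.1% without the library factor. In control trees 53 calls were made without August replicate 2 and 0 without August replicate 1 or either May replicate. In thinning trees 0 were made without either August replicate and 5250 were made without May replicate 1. In thinning plus shading 0 were made without any 1 of the 4 libraries.

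**Figure D2:**
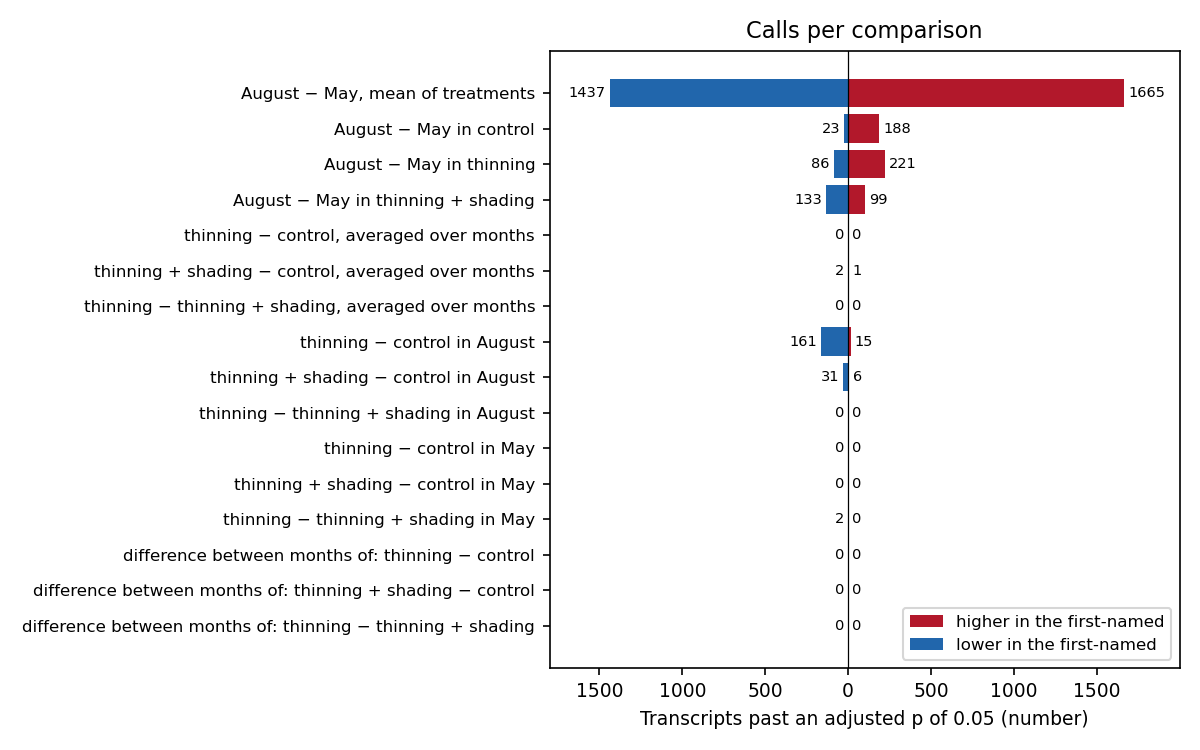
Number of transcripts past a limma adjusted p of 0.05 in each of the 16 comparisons of 19726 transcripts; bars to the right are higher and bars to the left lower in the group named first. The month effect averaged over treatments has 1665 higher and 1437 lower calls, and among comparisons of treatments, thinning against control in August has the most, with 15 higher and 161 lower.

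In August, thinned trees had lower levels than control trees of a set of transcripts that control trees held at high levels. This comparison addresses the relief from competition for water and light together. TRINITY_DN2743_c0_g1 was at 720 ± 165 scaled TPM in control and 2.90 ± 2.78 in thinning trees (mean ± SD, n = 2; log2 fold change -7.72, SE 1.36; limma adjusted p = 0.048). TRINITY_DN2778_c2_g1 was at 524 ± 103 and 1.93 ± 1.87 (log2 fold change -7.64, SE 1.28). TRINITY_DN15461_c0_g2 rose from 5.45 ± 0.89 in control to 56.7 ± 10.2 with thinning (log2 fold change 3.16, SE 0.37), and TRINITY_DN2971_c1_g2 rose from 8.40 ± 0.60 to 63.8 ± 13.5 (log2 fold change 2.77, SE 0.41). The rule left 8 higher and 116 lower transcripts to choose from. None of the 4 named transcripts kept its call without any 1 of the 4 libraries compared. Their log2 fold changes then kept their sign, from -8.52 to -6.92 for TRINITY_DN2743_c0_g1 and from 2.97 to 3.34 for TRINITY_DN15461_c0_g2. These calls pass narrowly: all 4 were lost in the fit of only the groups compared (limma adjusted p from 0.063 to 0.070), both lower ones also with a pseudocount of 0.5 (0.058 and 0.054) and with no filter (0.082 and 0.067), TRINITY_DN2743_c0_g1 also after quantile normalization (0.053) and with a filter of 50 (0.052), and TRINITY_DN2971_c1_g2 with no filter (0.051).

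Thinning against control in August gave 176 calls, 15 higher and 161 lower, in 145 components (limma, n = 2). The median log2 fold change of the lower calls was -3.38, and 148 of them were lower by 4-fold or more. Their median level was 72.5 scaled TPM in control trees in August, and between 4.23 and 8.14 in the other 5 groups, although 74 of the 161 had a mean of 10 or more in shaded trees in August, 70 in thinning trees in May and 54 in control trees in May. In 99.4% of the lower calls both control August libraries were above all 4 libraries of thinned trees in August, shaded or not, which the choice of these transcripts favours. Of the 176 calls, 9 were left without control August replicate 2, and 0 without control August replicate 1, thinning August replicate 1 or thinning August replicate 2. The count was 36 with a filter of 50, 67 in a fit of only the groups compared, 89 with a pseudocount of 0.5 and 350 with a pseudocount of 8.

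**Figure D3:**
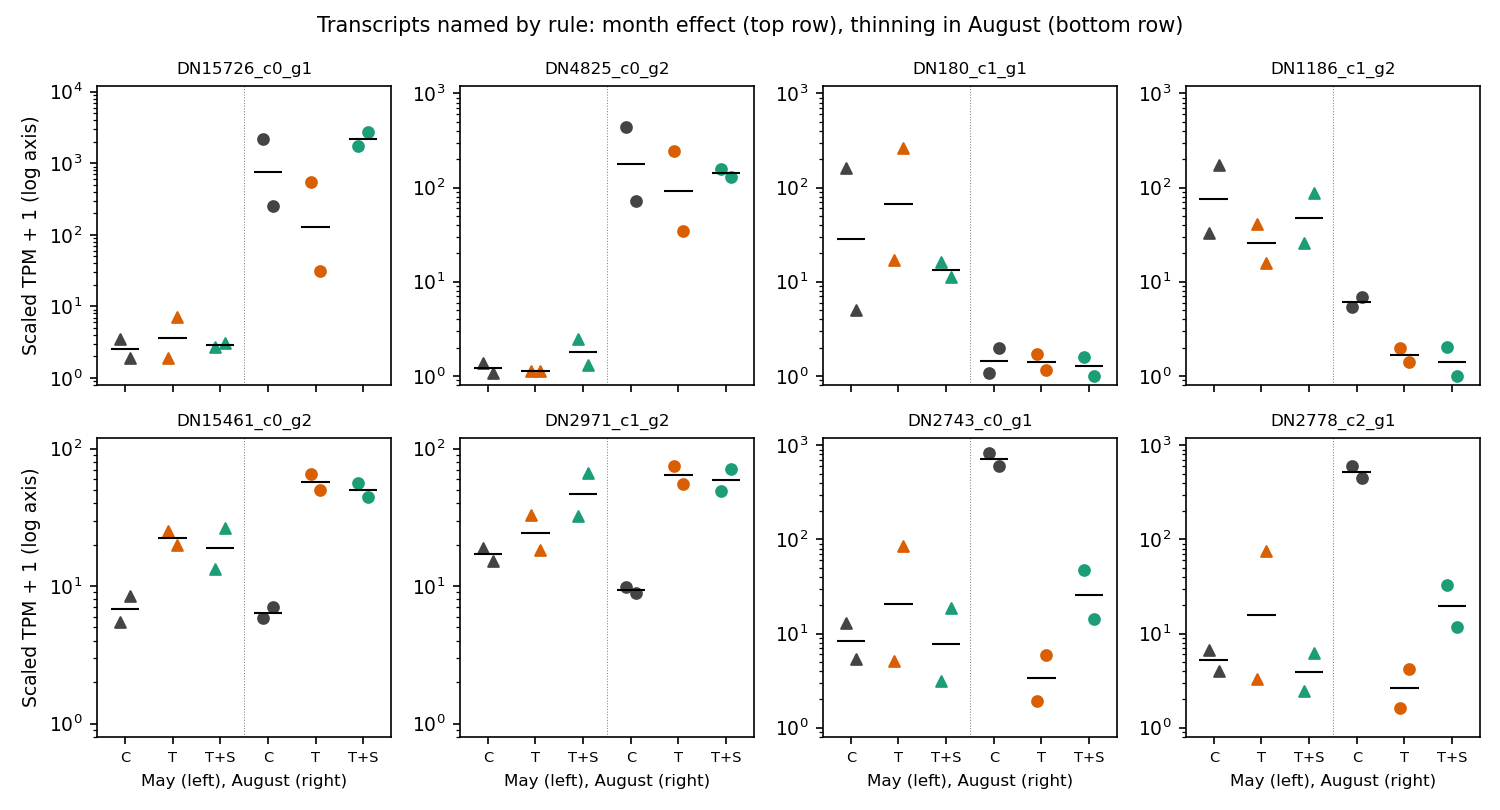
Scaled TPM + 1 on log axes of the 8 transcripts named by rule for the month effect (top row) and for thinning against control in August (bottom row); C is control, T thinning and T+S thinning plus shading. Each point is 1 library and each bar the geometric mean of 2 libraries, with May at the left and August at the right; TRINITY_DN2743_c0_g1 is at 836 and 603 in the control August libraries and at 84.2 or below in the other 10.

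Shaded trees in thinned stands differed from control trees in August in the same direction as unshaded ones, which addresses the relief from competition for water with light held low. TRINITY_DN3493_c0_g2 was at 147 ± 80 scaled TPM in control and 0.487 ± 0.076 in shaded trees (n = 2; log2 fold change -6.53, SE 0.74; limma adjusted p = 0.033). TRINITY_DN1076_c0_g1 was at 114 ± 41 and 0.338 ± 0.128 (log2 fold change -6.39, SE 0.85). TRINITY_DN689_c0_g1, the only higher transcript that met the rule, rose from 23.1 ± 7.7 to 139 ± 3 (log2 fold change 2.58, SE 0.30) and stood at 111 ± 0.3 in unshaded thinned trees. All 3 were lost in the fit of only the groups compared (limma adjusted p from 0.134 to 0.167), and both lower ones with a pseudocount of 0.5 (0.051 and 0.074) and with a filter of 50 (0.17 and 0.189). None of the 3 named transcripts kept its call without any 1 of the 4 libraries compared. Their log2 fold changes then kept their sign, from -7.11 to -5.95 for TRINITY_DN3493_c0_g2 and from 2.25 to 2.91 for TRINITY_DN689_c0_g1. Thinning plus shading against control gave 37 calls, 6 higher and 31 lower. Without control August replicate 2 there were 8 calls, 6 of them among the 37; there were 2 without thinning plus shading August replicate 1, and 0 without control August replicate 1 or thinning plus shading August replicate 2. The count was 0 in a fit of only the groups compared, 7 with a filter of 50, 21 with a pseudocount of 0.5 and 259 with a pseudocount of 8.

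Of the 37 calls, 34 were also called with thinning alone in the same direction, 28 lower and 6 higher, and 0 in the opposite direction. Independent lists of these sizes would share 0.253 lower and 0.0046 higher transcripts, and with unchanged groups against the same control libraries at most 1 was shared in 100 simulations. The shared calls fell to 6 without control August replicate 2 and to 0 without replicate 1. Across transcripts, the log2 fold changes of both treatments correlated at r = 0.769, against 0.501 for unchanged groups; their covariance was 0.577, against 0.123, a difference of 0.454. The controls were not split, since each part would hold 1 library, and part of the excess may come from sharing them. In the 161 transcripts lower with thinning, the median log2 fold change with thinning plus shading was -2.83, and 160 of them were below control in both shaded libraries. These transcripts were chosen for their values in the same control libraries; in 100 simulations with shaded trees like the control, the median was -0.15 or closer to 0.

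Between thinned trees with and without shading in August, which differ in light, 0 transcripts were called (limma; smallest adjusted p 0.051), and 904 of 19726 (4.58%) had an unadjusted p under 0.05. The median 95% confidence interval reached 0.866 log2 units to either side before adjustment. It rests, for each transcript, on 1 spread over both months, while the SD between replicates was 0.518 log2 units in August and 1.01 in May. A fit of the 6 August libraries alone gave 4 calls. A pseudocount of 0.5, a filter of 50 and TPM without the library factor gave 2 calls each. For thinning against control within August, which has the same number of libraries, 6.8% of simulated 2-fold and 52.9% of 4-fold changes were recovered. These shares are for the more abundant transcripts, and larger differences may also have been missed.

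In May, thinning against control gave 0 calls and 1679 transcripts at an unadjusted p under 0.05 (limma). Thinning plus shading against control gave 0 calls and 961 such transcripts. Without thinning May replicate 1, thinning against control gave 723 calls, with replicate 2 as the only thinning library. Between thinned trees with and without shading, 2 transcripts were called in May, both named after their values had been seen. TRINITY_DN464_c0_g1 was at 9.98 ± 0.85 scaled TPM in thinning and 112 ± 18 in thinning plus shading (n = 2; log2 fold change -3.35, SE 0.27; limma adjusted p = 0.012), with 71.0 ± 25.02 in control and between 122 and 165 in the August groups. TRINITY_DN5193_c0_g1 had nearly the same profile, at 9.14 ± 1.82 and 99.5 ± 5.7 (log2 fold change -3.32, SE 0.25). Both calls were lost in the fit of only the groups compared (limma adjusted p = 0.946), in the 6 May libraries alone (0.9) and with no filter (0.057). In simulations of thinning against control in May, the test made a median of 103 false calls. That other comparison gave 0 calls in the data, so the number may not carry over. The count was 2439 without thinning May replicate 1, 7 without thinning May replicate 2, and 0 without either shaded May library.

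Averaged over both months, thinning against control gave 0 calls, with 2129 transcripts at an unadjusted p under 0.05, and thinning against thinning plus shading gave 0, with 817 (limma). Without thinning May replicate 1 or 2 the first count was 65 or 180, and the second 271 or 10. Thinning plus shading against control gave 3 calls, named after their values had been seen. TRINITY_DN2080_c0_g2 was listed at 0, 0.194, 0 and 0 in the 4 control libraries and between 6.84 and 28.1 in the 8 libraries of thinned trees, shaded or not. The log2 fold change with shading was 4.16 (SE 0.38; limma adjusted p = 0.043). TRINITY_DN41976_c0_g1 and TRINITY_DN41976_c0_g2, of 1 component, had log2 fold changes of -1.33 and -1.32. All 3 calls were lost after quantile normalization (limma adjusted p = 0.055 for the first and 0.067 for the others), and those of that component also with no filter (0.076). TRINITY_DN41976_c0_g1 was at 17.3 ± 0.7 scaled TPM in shaded trees in August, against 70.3 ± 0.9 in unshaded thinned trees and 84.5 ± 11.6 in control trees (n = 2), and at 88.5 ± 2.5 in shaded trees in May. The 3 calls were lost without any 1 of the 8 libraries compared; without thinning plus shading August replicate 1 there were 6 calls, of other transcripts.

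Whether the treatment differences themselves changed between months was tested directly. The difference between months gave 0 calls for thinning against control, for thinning plus shading against control and for thinning against thinning plus shading, with 1768, 988 and 1705 transcripts at an unadjusted p under 0.05 (limma). The larger number of calls in August is therefore not shown to be a difference between the months. Without thinning May replicate 1 the first of these counts was 582 and the last 1321. With a pseudocount of 8 the first was 129 and the second 21. Of the 176 transcripts called with thinning in August, 46 (26.1%) had the same sign in May, and 20.5% or 55.1% without thinning May replicate 1 or 2, against 52.5% of all tested transcripts. Of the 37 called with thinning plus shading, 26 (70.3%) had the same sign in May, against 58.0% of all. The August and May differences between thinning and control correlated across transcripts at r = 0.029, at -0.124 without thinning May replicate 1 and at 0.176 without replicate 2.

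Thinning May replicate 1 differed from the other 11 libraries in transcripts outside the tested set. It listed 63046 transcripts that were at 0 in every other library, against 1153 to 7861 for any other library, and these held 10.9% of its summed value, against at most 1.71%. Of these transcripts, 105 were at 10 or more, against at most 16 in any other library.

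**Figure D4:**
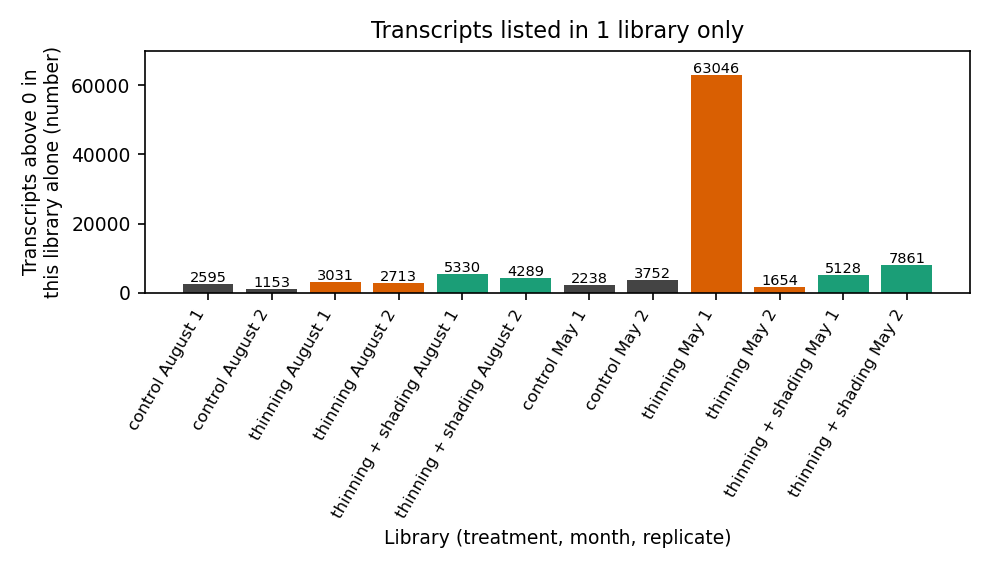
Number of transcripts above 0 in 1 library and at 0 in the other 11, for each library by treatment, month and replicate, coloured by treatment. Thinning May replicate 1 has 63046, and the other 11 libraries have between 1153 and 7861.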

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

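The tests of sequencing depth and of RNA from another organism in thinning May replicate 1, of swapped months, of mixed-up May treatments and of 1 deciding control library were chosen only after the results had been seen.

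Thinning May replicate 1 stands out for 63046 transcripts that are above 0 in it and in none of the other 11 libraries, which is data outside the tested set. Deeper sequencing alone stays open. Of these transcripts 105 were at 10 or more, a level where other libraries have at most 16 of their own. Those 16 were among only 7861 in thinning plus shading May replicate 2. The larger number may therefore only follow the larger set of 63046. RNA of another organism on or in that needle sample is a candidate explanation, since these transcripts hold 10.88% of the library's summed value, but it stays open because no sequences were used here. Fir RNA at a low level in every library also stays open: its test was void, because the median ratio it relies on was 0 in all 12 libraries. The mean ratio was 2.57 in this library and at most 0.938 in the others. Each ratio used its own transcripts, 187312 here and 252071 to 260988 for the others, whose choice involved this library. These mean ratios are therefore not on equal terms. A biological difference of the trees sampled was not tested.

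Calls between treatments were made in August and almost none in May, and a swap of libraries between the months is argued against, since 0 libraries correlated best with a library of the other month. The wider spread of the May replicates stays open. August differences placed on May spreads were called in 51.1% of the 176 cases. Over 100 draws the number ran from 73 to 105, on both sides of the bound of 50% set beforehand. With August spreads only 38.6% were called. The simulation lowered transcripts from their mean over all 12 libraries and cut values at 0, so that large falls were shortened. Neither percent can therefore decide on the May spread. A test added after the results had been seen used the first residual component as a covariate. The spreads were then 0.513 in August and 0.533 in May, and thinning against control gave 735 and 10 calls. It cannot decide, since the component comes from the residuals that the test uses. Mixed-up treatment labels in May may contribute and stay open. Exchanging 1 control with 1 thinning library raises the lowest replicate correlation from 0.407 to 0.830. This exchange was picked as the best of 15 pairings of the May libraries, which favours a rise. With this exchange, the May difference has 1 relation to the August sign, the same or the opposite, in 79.55% of the August thinning calls. The bound of 75%, set before this share was computed, was passed. Which of the re-made groups would be the thinned one is open, so the direction of this share is not given. That evidence is weak. An earlier bound, that the lowest pair reach the 0.903 of the August pairs, was not met. As labelled, the share counted in the same way is 73.9%, for the opposite sign, since 26.1% of those calls had the August sign in May. The 2 shares can stand for unlike directions, so their closeness says little. A stricter bound on the gain over the labelled share, tried afterwards, was missed. The shaded May replicates, which no such exchange touches, also differ along the same axis (r = 0.640). A change between the 2 sampling dates in the response to thinning also stays open, and the direct test of it gave 0 calls.

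The transcripts lower with thinning in August had a higher median in control trees of that month than in any other group. One of the control libraries being the whole source is argued against, since 85.79% of the transcripts lower by 2 log2 units or more in 1 pair of thinning and control libraries, and 90.0% in the reverse choice, were also lower in the other pair, which shares no library with it, against 53.0% or less of all transcripts. Leaving out 1 library ended nearly all calls whichever it was, with 0 left without control August replicate 1 or either thinning August library and 9 without control August replicate 2, while the log2 fold change of TRINITY_DN2743_c0_g1, for one, stayed between -8.52 and -6.92; replicate 1 was higher in the called transcripts by a median of 0.66 log2 units, against 0.006 in others. RNA of another organism on the control trees stays open. The number of transcripts at 1 or more in both control August libraries and at 0 elsewhere was 228, within the 105 to 366 of the other groups. That count cannot decide, since only 14 to 37 of the 161 lower calls had a mean under 1 in any 1 other group. An organism present in every group would also escape it. At a higher level the count differs: 29 transcripts were at 10 or more in both and under 1 in all other libraries, and 0 in any other group. An organism with few abundant transcripts is therefore not excluded for those. A response of unthinned trees to late summer, which may be the source, was not tested.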

How the results depend on the processing

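TPM without the library factor, the residual component as a covariate, fits of 1 month and crossed pairs were tried only after the data had been seen. The planned tests on whole reads were not run, since the values hold no reads. Of the counts of calls recomputed, 129 stayed within 1.5 times of the reported count, 70 fell and 62 rose beyond it. Most of the 129 were reported counts of 0 that stayed at 0, so this number says little about how stable the calls were. Of the named transcripts' values, 174 kept their direction and call, 143 kept the direction and lost the call, and 2 turned: TRINITY_DN7298_c0_g1 and TRINITY_DN7298_c0_g2 had log2 fold changes of 0.37 and 0.39 between the months after quantile normalization, which gives the top rank of every library 1 value. The cause was not tested for the changes below unless it is stated. Depth is unknown, and what it limits cannot be given.

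Quantile normalization gave 381 calls for the month effect in control, 141 in thinning plus shading, and 0 for shading against control averaged over months. A pseudocount of 0.5 gave 137 for the month effect in control, 89 and 21 for thinning and for shading against control in August, 19 shared by both, and 2 for thinning against shading in August. A pseudocount of 8 gave 463 for the month effect in control, 350 and 259 for thinning and shading against control in August, 224 shared, 58 and 44 averaged over months, and 129 and 21 for their differences between months. With no filter there were 770 calls for the month effect, 357, 3 and 0 within control, thinning and shading, 23 and 9 for thinning and shading against control averaged over months, 315 and 192 in August, 175 shared, 11 for the difference of thinning between months, and 0 for thinning against shading in May; more transcripts near 0 were then tested. With a filter of 50, under which fewer transcripts were tested, there were 1003 for the month effect, 41 and 125 within control and thinning, 36 and 7 for thinning and shading against control in August, 5 shared, 2 for thinning against shading in August and 2 averaged over months, and 2 for thinning against control in May. Fits of only the groups compared, which have fewer samples, gave 9, 0 and 0 for the month effect in control, thinning and shading, 67 and 0 for thinning and shading against control in August, 1 and 11 averaged over months, and 0 for thinning against shading in May.

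Without the library factor there were 4862 calls for the month effect, 550, 1597 and 527 within control, thinning and shading, 6 for shading against control averaged over months, and 2 for thinning against shading in August; the factors differ between the months. With the residual component there were 8046 for the month effect, 2576, 5205 and 2378 within control, thinning and shading, 735 and 662 for thinning and shading against control in August, 451 shared, 267 and 607 averaged over months, 10 and 2 in May, 2, 252 and 11 for thinning against shading in August, in May and averaged, and 392 and 301 for the differences between months of thinning against control and against shading. This component was taken from the same residuals that the test uses, so these counts are too high to be read as calls. The 6 August libraries alone gave 282 and 179 for thinning and shading against control, 141 shared and 4 for thinning against shading, and the 6 May libraries 0 for thinning against shading.

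The replicate numbers did not pair the samples: of 15 pairs of groups, same-numbered libraries deviated together in 5 (r over 0.1) and apart in 6 (under -0.1), from -0.707 to 0.629. The replicate block gave 2358 calls for the month effect, 85, 10 and 43 within control, thinning and shading, 9 and 8 for thinning and shading against control in August, 5 shared, 0 for shading against control and 2 for thinning against shading averaged over months, and 2 for thinning against control in May. Crossed pairs as a block gave 0 calls for the month effect in control and 0 for shading against control in August.

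Leaving out 1 library at a time, which leaves a group with a lone library assumed to vary like the others, gave 1327 to 6468 calls for the month effect, 0 to 53 in control, 0 to 5250 in thinning and 0 to 0 in shading. In August it gave 0 to 9 for thinning and 0 to 8 for shading against control and 0 to 6 shared. In May it gave 0 to 723 for thinning against control and 0 to 2439 for thinning against shading. Averaged over months it gave 0 to 180 for thinning and 0 to 6 for shading against control and 0 to 271 for thinning against shading. The differences between months ranged from 0 to 582 for thinning against control and from 0 to 1321 for thinning against shading. All the highest values in May and in the differences between months came without thinning May replicate 1.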

Other observations

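The splits of the samples were planned, and the hypothesis on the month effect was set before its test.

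One hypothesis was that thinning lowers transcripts that are otherwise higher in August than in May. Of the 161 transcripts lower with thinning in August, 129 (80.12%) were higher in August than in May in the shaded trees, which share no library with that comparison, against 47.2% of all tested transcripts. The share was 79.5% and 80.1% without 1 or the other shaded May library. This is consistent with the hypothesis, but 15 of the 15 transcripts higher with thinning also had a positive month effect there, so a tendency of all August calls to be higher in August may explain it as well. The mirror test, of the 31 transcripts lower with shading in the unshaded thinned trees, gave 35.5% against 48.4% of all and goes the other way.

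Other splits of the samples were counted for each comparison with at least 3 libraries per side. For the month effect, 1 of 100 splits within treatments, the real one, gave as many as 3102 calls, and the highest of the others gave 9. The other splits mix August and May libraries within a group, which widens the spread and lowers the calls. A chance division of these libraries is argued against. A chance difference between the samples taken on each date is not excluded. For thinning against control averaged over months, all 18 of 18 splits gave at least the real 0 calls, and the highest of the others gave 2383. That split puts thinning August replicates 1 and 2 with thinning May replicate 1 and control May replicate 2, which points to a structure of the May libraries that their treatment labels do not follow. For thinning plus shading against control the real split gave 3 calls, 1 of 18 splits reached that, and the highest of the others gave 2. For thinning against thinning plus shading, 18 of 18 splits reached the real 0 and the highest of the others gave 2. With 18 splits no share under 0.05 is possible.

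The first component of the residuals held 64.7% of the variance left within groups and lay almost wholly in May. Its score was 2.01 in thinning May replicate 1 and -2.01 in replicate 2, -1.13 and 1.13 in the control and 0.793 and -0.793 in the shaded May replicates, and no more than 0.140 away from 0 in any August library.

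The 72972 transcripts at 1 or more in thinning May replicate 1 and under 1 in every other library had a mean of 2.23 scaled TPM there, a mean of 0.076 in thinning plus shading May replicate 1, 0.069 in control May replicate 2, and 0.017 or less in the other 9 libraries.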
